A study of Mus musculus with 24 samples.

How the data were processed

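RNA of lung, heart, spleen, testis, skeletal muscle and brown adipose tissue from Nur77 knockout mice was compared with RNA of the same organs from wild-type mice on 2-colour cDNA arrays. Nur77 is the protein of the gene Nr4a1, an orphan nuclear receptor of the NR4A family. Per the labels' design text, 7 mutant mice were pooled and hybridised repeatedly against a pool of 7 wild-type mice. The labelling protocol speaks of a control pool of 6 animals, and this difference could not be settled. Each organ has 4 arrays, 24 in all. The mutant pool carried Cy5 on 2 arrays of each organ and Cy3 on the other 2. Per the labels' protocols, 20 µg of total RNA was reverse transcribed and labelled indirectly.

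The values analysed are the authors' deposited log2 ratios, 1 per probe and array. Their scale, centring and direction, the filter behind the empty cells, the background correction and the software are not given in the sources used here. The log base was read as 2 because 4874 of the 392774 values lie in a separate mode with sizes of 15.70 or more, near the log2 of a 16-bit signal over about 1, and no value lies between 9.94 and 15.70. All 4874 have the sign of Cy5 over Cy3 if positive means mutant over wild type. Arrays of different organs correlated at a median Spearman rho across probes of 0.059 where the dye orientation was the same and of -0.040 where it was opposite. Arrays of the same organ correlated at a median of 0.116 with the same dye orientation and of -0.045 with opposite ones (from -0.231 to 0.101), so at the median the repeats of 1 comparison did not correlate positively once the dyes were exchanged, and these values decide the orientation only weakly. The ratios were taken as already turned to mutant over wild type on every array, and none was turned again. This direction is likely but not stated. Array medians ranged from -0.78 to 0.67 and were not centred in the main analysis. The values of the separate mode, 1.24% of all, were treated as not measured.

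Of 20205 probes, 13891 have 1 gene symbol in the platform annotation table, 5 have several and 6309 have none there. The Entrez number of 13855 probes was found in the RefSeq gene table (GRCm38.p6), which changed no symbol. Probes with the same single symbol were averaged per array (2969 of 9834 genes had several), and probes without a symbol stayed as rows of their own, which gave 16148 rows. A row was tested in an organ where at most 1 of the 4 arrays lacked a value and both dye orientations had one, and in tests over organs where this held for every organ.

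Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. One model over the 24 arrays held 6 organ coefficients and 1 dye term. Benjamini-Hochberg adjustment was made within each organ, with a threshold of 0.05. The 4 arrays of an organ are repeats of 1 comparison between 2 pools. Their p-values therefore measure the difference between these pools against the error between hybridisations, and say nothing on the spread between animals. The number of arrays limits the precision. Differences between organs were tested with limma's F test. For a difference recurring over organs, the arrays of each organ were averaged first and the 6 organ means were tested. Lists of genes were tested with limma's camera (preset correlation 0.01), 40 lists in each organ where at least 5 genes were measured, adjusted over all 216 pairs of list and organ. Standard errors are those of the model. Within an organ they come from the fit with 1 spread for all organs, also beside an adjusted p with array weights (described below).

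The lists, the tests, the alternatives not named otherwise below and the rule for named genes were fixed before the data were examined. The rule names Nr4a1, Nr4a2 and Nr4a3. In each organ it names the 10 highest and 10 lowest log2 ratios among genes with 1 symbol that pass the test with 1 sign on every array. Where fewer than 5 pass in a direction, it gives the 5 largest ratios with 1 sign on every array as values. It further names up to 4 members of a list that shifted or has members past the test, the 5 largest mean ratios in each direction with 1 sign in all organs, and the 10 genes with the smallest adjusted p between organs. Of the list members the rule names, those that did not pass are given only for lists that shifted. Names outside the rule are said to be so.

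Heart replicate 2 has a wild-type channel labelled skeletal muscle. It was to be left out if the cardiac and skeletal muscle lists differed on it by more than 2 times the largest difference on the other arrays. The medians differed by -0.09, against at most 1.36 elsewhere, and it was kept.

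The procedure was tested on simulated data with the real pattern of missing values and 200 changed genes per organ. With an equal spread in all organs, the skeletal muscle comparison (11974 rows) recovered 86.4% of changes of log2 size 4, 43.3% of size 2 and 8.96% of size 1, with 2 false calls. With the organs' real differences in spread, the same model made 118 false calls among 232 in skeletal muscle and 83 among 184 in spleen (11217 rows). Array weights with 1 variance per organ made 2 false calls among 61 and 4 among 62. They made 11 among 144 in heart, 9 among 111 in testis and 8 among 119 in brown adipose tissue. The shared model made 1 among 90, 2 among 93 and 0 among 76 there. The simulated spread had 1 factor per organ, the form that these weights fit, so the simulation favoured them. Differences in spread between the arrays of 1 organ were not simulated. The median residual SD was 1.07 in skeletal muscle and 1.03 in spleen, against 0.51 in heart and 0.52 in brown adipose tissue. For this reason the array weights, an alternative fixed beforehand, are named beside the results.

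Other alternatives were no dye term, a dye term per organ, each organ fitted alone, arrays centred and scaled, probes taken singly, only complete rows, each array left out, the replicate number as a block, camera on ranks, only replicates 1 and 3 across organs, and heart replicate 2 left out. Scaling gave every array the same spread. It therefore shrank ratios in organs of wide spread, such as skeletal muscle, and enlarged them in brown adipose tissue. Chosen after seeing the data were keeping the separate mode, centring without scaling, array weights for lists, leaving out the 2 most shifted skeletal muscle arrays, and leaving out the pancreas genes. Treating the separate mode as not measured in the main analysis was also decided after its values were seen. No rule on these values had been fixed beforehand.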

Results

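Gene expression of Nur77 knockout mice was compared with that of wild-type mice in 6 organs, to find which genes differ in each organ when this nuclear receptor is missing. Nr4a1, which encodes Nur77, is an immediate early gene with known roles in T cells, muscle metabolism and steroid-producing cells. Each organ was represented by 4 two-colour arrays, a mutant pool against a wild-type pool, with the dyes exchanged on 2 of them. The arrays held between 13396 values (spleen) and 19455 values (brown adipose tissue) for 20205 probes. All ratios below are log2 of mutant over wild type, a direction that is likely but not stated with the values. Arrays of 1 organ correlated weakly, at a median Spearman rho across probes of 0.116 with the same dye orientation and of -0.045 with opposite ones.

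Nr4a1 itself was lower in the mutant pool on 21 of the 22 arrays that measured it. The ratio was -1.73 ± 0.31 (SE) in skeletal muscle, a level 3.32-fold lower, and -1.14 ± 0.26 in brown adipose tissue, 2.20-fold lower. It was -0.75 ± 0.26 in spleen, -0.67 ± 0.26 in heart, -0.38 ± 0.26 in lung and -0.24 ± 0.31 in testis. By limma's moderated test, without adjustment across genes, p was 2.33e-05 in skeletal muscle, 0.000424 in brown adipose tissue, 0.011 in spleen, 0.0203 in heart, 0.163 in lung and 0.444 in testis. By these unadjusted p-values Nr4a1 fell in 4 organs and did not pass in lung and testis. Adjusted across genes, it passed in skeletal muscle only (limma, adjusted p = 0.0022). With array weights it passed in brown adipose tissue (adjusted p = 0.0107) and heart (0.0378). There it did not pass in skeletal muscle (0.149), spleen (0.816), lung or testis. The difference between organs did not pass either (F test, adjusted p = 0.135). The probe's position relative to the disrupted part of the gene is not given, and a probe outside it would check nothing. After centring and scaling the spleen value was -0.44 and did not pass. Skeletal muscle (-0.79) and brown adipose tissue (-1.82) changed their order, but scaling shrinks the first and enlarges the second, so these sizes are not comparable. With the values of the separate mode kept none of the 4 organs passed. Testis then passed in the opposite direction, at 4.13 (limma, unadjusted p = 0.0309), where 1 of its values lies in that mode. In heart it did not pass without replicate 1 (-0.63) or 4 (-0.61), nor in spleen without replicate 3 (-0.64), and the lung value was -0.15 without replicate 3. The relatives Nr4a2 and Nr4a3 followed the dye, with dye terms of -1.72 and -2.30 (limma, unadjusted p = 0.000236 and 1.26e-06 over all arrays with a value). Nr4a3 was at 0.88 ± 0.67 in lung, 1.10 ± 0.67 in spleen and 0.33 ± 0.57 in skeletal muscle, and Nr4a2 at 0.12 ± 0.55 in lung and -0.38 ± 0.55 in skeletal muscle. Neither passed in any organ where it was tested, and the signs of several of these values turned with the treatment of the dye or of single arrays. In testis Nr4a2 had values on 2 arrays only, too few for the test. It was below 0 there with both dyes, at -3.70 with the mutant pool in Cy5 and -1.99 in Cy3.

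**Figure D1:**
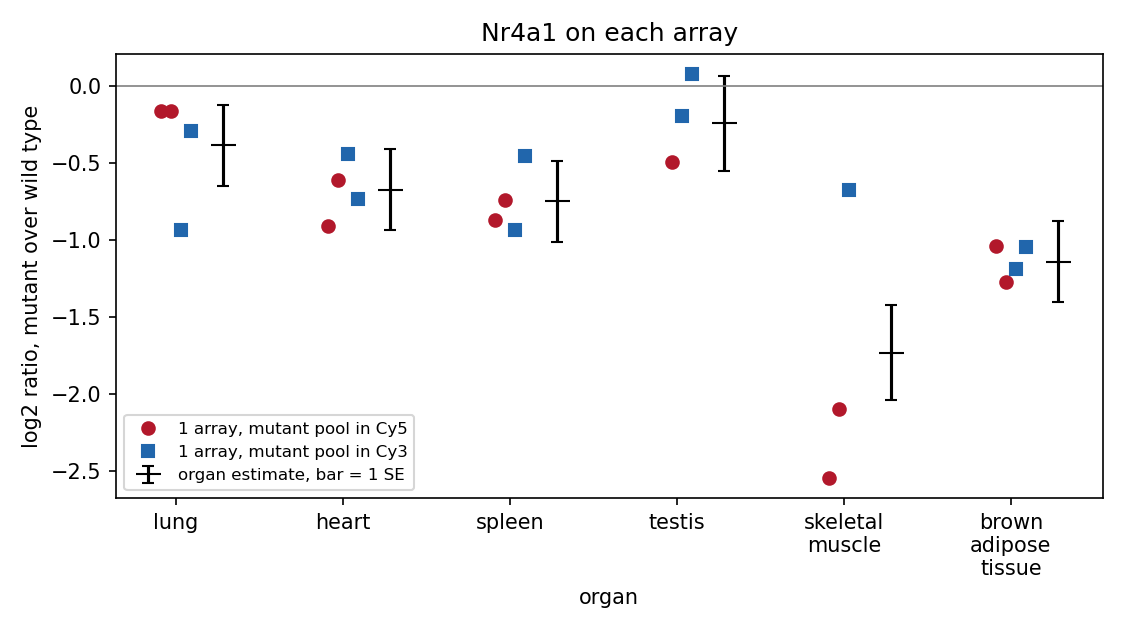
Log2 ratio of Nr4a1 (mutant over wild type, vertical axis) on each array by organ, with circles for arrays with the mutant pool in Cy5, squares for Cy3, and a dash with a bar of 1 SE for the organ's estimate. The 4 brown adipose tissue arrays lie between -1.27 and -1.04, and 1 testis array lies above 0, at 0.08.

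In spleen, genes of the exocrine pancreas were far lower in the mutant pool. Cela2a, an elastase, had a ratio of -6.68 ± 0.54, a level 103-fold lower. The protease genes Ctrl (-6.23 ± 0.41), Ctrb1 (-5.83 ± 0.46), Cela3b (-3.87 ± 0.25) and Cpa1 (-3.44 ± 0.28), the lipase cofactor Clps (-5.70 ± 0.56), the lipase relative Pnliprp1 (-4.26 ± 0.45), the zymogen granule gene Zg16 (-5.24 ± 0.26) and the trypsin inhibitor Spink1 (-3.61 ± 0.30, a name outside the rule) fell as well, on all 4 arrays. Of 11 measured genes of the pancreas list, 9 fell and none rose over all genes tested. Adjusted over the list alone, 10 fell and 1 rose. Sycn stood at -1.90 and Cpb1 at 1.89, and the 2 probes of Pnliprp1 at -4.90 and -0.01. The list median was -4.26 (camera adjusted p = 1.35e-29), and -2.62 after centring and scaling. With an estimated correlation the camera adjusted p was 7.85e-30, but the estimate, 0.00915, lay below the preset 0.01. This list holds markers of a neighbouring tissue that can be carried over with spleen. In the other organs its median lay between -0.46 and 0.06.

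Outside the pancreas list, Tff2, a trefoil peptide, fell in spleen (-4.14 ± 0.44), and Akr1b8, an aldo-keto reductase, fell as well (-3.91 ± 0.25). Whether they fell for the same reason as the pancreas genes was not tested. Naa80, an actin acetyltransferase, fell (-4.40 ± 0.82), but not with array weights (adjusted p = 0.558). Ribosomal protein genes were lower as a group, with a median of -0.67 over 45 measured genes. Camera gave an adjusted p of 7.89e-11, and the shift did not pass with an estimated correlation (adjusted p = 0.108). Relative to all genes on the array, the list median was -1.72 on replicate 4 and -0.45, -0.08 and -0.36 on replicates 1 to 3, and without replicate 4 of the organs the list median was -0.54 (camera adjusted p = 0.000231 at the preset correlation). After centring and scaling it was -0.34. Of the 45, 5 fell and none rose over all genes: Rpl35 (-2.83 ± 0.21), Rpl37a (-1.16 ± 0.24), Rpl37 (-1.08 ± 0.22), Rps15 (-1.07 ± 0.21) and Rps21 (-1.07 ± 0.24, outside the rule). With array weights Rpl35 alone passed among the 5, and its 3 probes ranged from -6.47 to -0.96. Adjusted over the list alone, 18 fell.

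Heat shock genes also shifted down in spleen, with a median of -0.86 over 10 genes (camera adjusted p = 0.0243). With an estimated correlation the camera adjusted p was 0.0197, but the estimate was 0, below the preset 0.01. The median was -0.39 without replicate 2 of the organs and -0.47 after centring and scaling. Hsph1, a chaperone of the Hsp110 group, fell by 1.56 ± 0.29, but not with array weights (adjusted p = 0.513). Hspd1 had a ratio of -1.87, Dnajb1 of -1.25 and Bag3 of -1.18. Adjusted over the list alone, 4 fell. The shift did not pass when any single replicate number was left out of the organs (adjusted p from 0.111 to 0.27), nor with only complete rows (adjusted p = 0.0772), with arrays centred only (0.0535) or with the separate mode kept (0.0663). The list of oxidative phosphorylation had a median of -0.31 over 45 genes, none past the test and 1 lower when adjusted over the list alone. Its camera adjusted p was 0.0368, and the adjusted p = 0.565 with an estimated correlation. The largest ratios were those of Ndufs8 (-1.53), Ndufa9 (-1.35), Atp5b (1.22) and Atp5c1 (-1.21). Relative to all genes the list median was -0.25, 0.19, 0.00 and -0.82 on the 4 arrays. It did not pass without replicate 1, 2 or 4 (adjusted p of 0.254, 0.0861 and 0.489), after centring and scaling (0.141), with arrays centred only (0.197) or with the separate mode kept (0.0744).

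Other lists had 1 or 2 members past the test in spleen. Of the list of fatty acid synthesis and white fat, Scd2, a stearoyl-CoA desaturase (-1.99 ± 0.35), and Thrsp, a regulator of lipid synthesis (-1.52 ± 0.26), fell, 2 of 14 genes. Dbp, a transcription factor of the circadian output, rose (1.17 ± 0.27, on 3 of 4 arrays), 1 of 9 genes of its list. Glul, glutamine synthetase, rose (1.44 ± 0.28), 1 of 11 genes of the glucocorticoid response, and Cidea, a lipid droplet gene of brown fat, rose (1.56 ± 0.39), 1 of 17. Tnni2 fell (-1.78 ± 0.39), 1 of 16 genes of the skeletal muscle list, and Myh7 rose, 1 of 8 of the slow muscle list. Adjusted over the list alone, the counts were the same except for 2 lower in the skeletal muscle list. None of these 6 lists shifted (camera adjusted p from 0.229 to 0.995), and none of these genes passed with array weights (adjusted p from 0.117 to 0.628).

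The 10 highest spleen ratios past the test were led by Myh7, the slow and cardiac myosin heavy chain (3.62 ± 0.86, 12.3-fold), Ppp2r2c (3.52 ± 0.76) and Sh3gl2 (3.17 ± 0.76). The others were Kndc1, Gnpnat1, Ppp1cc, the dopamine receptor Drd4, the neurofilament Nefh, Tomm34 and Cst9, at 2.53 to 2.99. Of the 10, only Kndc1 (2.99 ± 0.46) passed with array weights (adjusted p = 0.0412). The 2 probes of Tomm34 went opposite ways, at -0.34 and 4.26. In all, 172 of 11217 rows passed in spleen, 67 higher and 105 lower. With array weights 21 passed, 4 higher and 17 lower, all among the 172, and 21 passed after centring and scaling, 3 higher and 18 lower. Without replicate 1 the count was 289, without replicate 4 it was 300, and with spleen fitted alone it was 0.

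**Figure D2:**
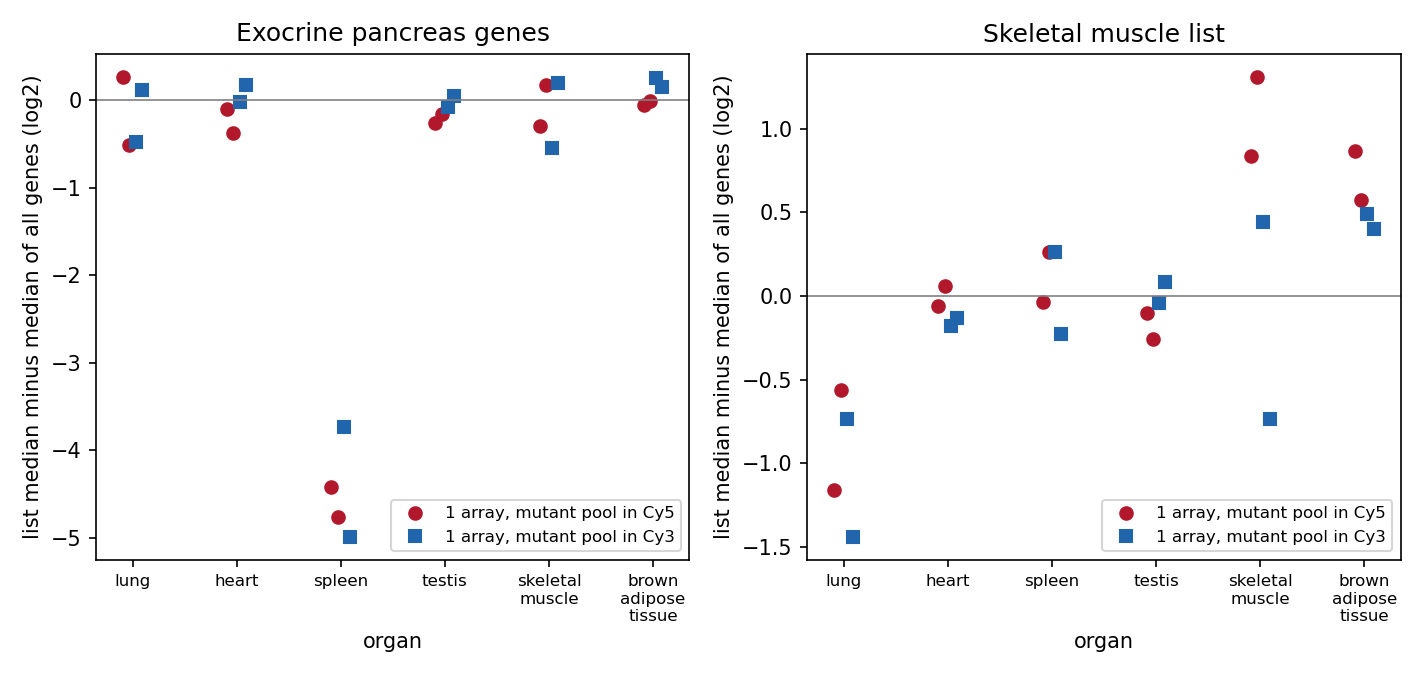
Median log2 ratio of the exocrine pancreas list (left) and of the skeletal muscle list (right) minus the median of all genes on the array (vertical axes), 1 point per array, by organ and dye of the mutant pool. On the 4 spleen arrays the pancreas list lies between -4.99 and -3.74. The muscle list lies between -1.44 and -0.57 on the lung arrays and between 0.40 and 0.87 on the brown adipose tissue arrays.

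In lung, genes of the skeletal muscle list were lower in the mutant pool. Tnnc2 (fast troponin C) fell by 3.46 ± 0.54, Tnni2 (fast troponin I) fell by 1.99 ± 0.34 and Myoz1, a Z-disc protein, fell by 1.96 ± 0.29, each on all 4 arrays. Of 19 measured genes of the skeletal muscle list, 3 fell and none rose. Adjusted over the list alone, 9 fell and 1 rose. The list median was -0.97 (camera adjusted p = 3.64e-09; 0.000412 with an estimated correlation). Of the 6 members above 0, Mylpf, a fast myosin light chain, had the highest ratio, 2.19 ± 0.51, and did not pass over all genes. Myl2, the regulatory myosin light chain of slow and cardiac muscle, rose by 1.61 ± 0.25, on all 4 arrays, a 3.05-fold difference. This was the only rise past the test in lung, 1 of 8 genes of the slow muscle list, also when adjusted over the list alone (camera adjusted p = 0.377). It did not pass with no dye term or with arrays centred only, where no row rose.

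Other genes that fell in lung were Lce1i, of the cornified envelope family (-2.68 ± 0.35), Hpca, a neuronal calcium sensor (-1.96 ± 0.36), and Thrsp, a regulator of lipid synthesis (-1.28 ± 0.22), 1 of 16 genes of the list of fatty acid synthesis and white fat, also when adjusted over the list alone (camera adjusted p = 0.457). Heat shock genes shifted down, with a median of -0.64 over 10 genes (camera adjusted p = 0.00508). With an estimated correlation the camera adjusted p was 0.00382, but the estimate was 0, below the preset 0.01. None passed over all genes and 2 fell when adjusted over the list alone, Hsph1 (-0.91 ± 0.29) and Dnaja1 (-0.80 ± 0.25). Hspd1 had a ratio of -1.46 and Dnajb1 of -0.99. The shift did not pass without replicate 2, 3 or 4 of the organs (adjusted p of 0.053, 0.121 and 0.0933) or with the separate mode kept (0.0885). The largest positive ratios with 1 sign on every array that did not pass were those of Cgref1 (3.16), Asah1 (2.92), Pfkfb2 (2.91), Paqr7 (2.80) and Gar1 (2.69). Of these, Cgref1 alone passed with array weights (adjusted p = 0.00802). In total 10 of 12365 rows passed, 1 higher and 9 lower, 3 of them without a symbol. With array weights 18 passed, 4 higher and 14 lower, among them the same 10. The count was 22 without replicate 1, 25 with a dye term per organ, 5 with arrays centred only and 0 with lung fitted alone.

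In skeletal muscle, 669 of 11974 rows passed, 402 higher and 267 lower, and the size of this number depended on how the spread was modelled. With array weights 36 passed, 33 higher and 3 lower, and after centring and scaling 60 passed, 58 higher and 2 lower, all of them among the 669. With arrays centred only, 552 passed, 447 higher and 105 lower, of which 466 were among the 669. Without replicates 2 and 4, the arrays with the most shifted medians, 300 passed. With skeletal muscle fitted alone 0 passed (limma), against 2414 rows at an unadjusted p under 0.05 in the shared model. The median of all genes was -0.16 before centring. Rps16, a ribosomal protein gene, had the highest ratio among genes with a symbol that passed, 3.55 ± 0.45 or 11.7-fold, on all 4 arrays, and passed with array weights (adjusted p = 0.0333). So did Dcaf13 (2.26 ± 0.23), a factor of ribosome formation, Ago2 (1.61 ± 0.20), of the RNA silencing complex, and Fam120b (1.77 ± 0.22). Of 14 genes of the T cell list, Ccr7, a chemokine receptor, fell by 2.85 ± 0.44 on 3 of 3 arrays and Gata3, a transcription factor, rose by 1.85 ± 0.38 on 3 of 3, the same count as when adjusted over the list alone. With array weights Ccr7 passed (adjusted p = 0.0293) and Gata3 did not (0.376), and the list did not shift (camera adjusted p = 0.97).

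The other genes with the largest muscle ratios passed the test but not with array weights (adjusted p from 0.129 to 0.914). Higher were Csad (3.54), of taurine synthesis, the testis histone H1f6 (3.47), Camk2a (3.38), a calcium-dependent kinase, the mitotic genes Tpx2 (3.19) and Kif20b (2.70), Foxn2 (2.91), Steap3 (2.89), Cited4 (2.75) and Ddx54 (2.70). Lower were Serpinb1a (-4.21 ± 0.72), a protease inhibitor, Ccdc124 (-4.07 ± 0.54), St3gal2 (-3.47), the translation factor Eif4g2 (-3.31), Ablim3 (-3.27), Apbb1 (-3.11), Fgf12 (-3.11), Numb (-3.07), the chromatin remodeller Chd8 (-3.04) and Frmpd1 (-2.88). With the values of the separate mode kept, Fgf12 stood at 0.21 and Frmpd1 at 1.90.

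Genes of oxidative phosphorylation shifted down in skeletal muscle, with a median of -0.59 over 50 genes. Camera gave an adjusted p of 0.000124, and the shift did not pass with an estimated correlation (adjusted p = 0.328). Of the 50, 9 fell and none rose over all genes, and 12 fell when adjusted over the list alone. ATP synthase subunits led, with Atp5g3 at -1.62 ± 0.44, Atp5l at -1.31 ± 0.23, Atp5j2 at -1.16 ± 0.27 and Atp5j at -1.09 ± 0.23. Relative to all genes on the array, the list median was -0.09 and 0.14 on the arrays with the mutant pool in Cy5, and -0.50 and -1.56 (replicate 4) on those with it in Cy3. Without replicate 4 the shift did not pass (adjusted p = 0.0941). No member passed with array weights. Relative to the median of all genes the list lay at -0.43, and after centring and scaling its median was -0.29. Fatty acid oxidation did not shift as a list (camera adjusted p = 0.726), while Acadvl (1.22 ± 0.23) and Hadha (1.06 ± 0.23), enzymes of mitochondrial beta-oxidation, rose, 2 of 17 measured members. Pdk2, a kinase that restrains pyruvate dehydrogenase, rose by 1.36 ± 0.22, 1 of 22 genes of glycolysis and glycogen use (camera adjusted p = 0.97). Of the skeletal muscle list Mybpc1, the slow-type myosin binding protein C (2.35 ± 0.51), Neb, the thin filament protein nebulin (2.04 ± 0.33), and Ryr1, the calcium release channel (1.63 ± 0.34), rose, 3 of 20, without a shift of the list (camera adjusted p = 0.143). The probes of Neb disagreed in sign, at -0.50 to 3.20. None of these 6 genes passed with array weights. For these 3 lists the counts were the same when adjusted over the list alone.

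Members of 15 further lists passed in skeletal muscle without a shift of the list (camera adjusted p from 0.108 to 0.97). Those that rose were Dbp, of the circadian output (2.03 ± 0.27, 1 of 10 clock genes), Glul (1.69 ± 0.28, 1 of 8 genes of the glucocorticoid response, its 2 probes at -1.69 and 5.07), the apoptosis genes Bid (2.00 ± 0.33) and Bak1 (1.29 ± 0.27, 2 of 11), and Mcm4, of DNA replication (1.88 ± 0.30, with Tpx2 2 of 16 proliferation genes). Psmd13 (1.61 ± 0.24, 1 of 21 proteasome genes), Cidea (1.84 ± 0.45, 1 of 17 brown fat genes), Icam1, an adhesion molecule (1.52 ± 0.37, 1 of 10 genes of inflammation), Slc4a1 (2.02 ± 0.52) and Tspo2 (1.40 ± 0.36, 2 of 13 erythroid genes) rose as well. Those that fell were the metallothionein Mt2 (-2.15 ± 0.47), Gsta4 (-2.09 ± 0.57, on 3 of 4 arrays) and Txn1 (-1.01 ± 0.21), 3 of 15 antioxidant genes. Mt2 is also the 1 that fell in the erythroid list and in that of the glucocorticoid response. Single members of other lists fell too, which were Smcp (-2.84 ± 0.59, 1 of 23 germ cell genes), Zfp36 (-1.11 ± 0.21, 1 of 11 immediate early genes), Herpud1 (-0.97 ± 0.24, 1 of 12 genes of the unfolded protein response), Ccn2 (-1.47 ± 0.37, 1 of 23 matrix genes) and Mylk (-1.63 ± 0.46, on 3 of 4 arrays, 1 of 8 smooth muscle genes, its probes at -3.16 to 1.72). Of 48 ribosomal genes, Rps16 rose and Rplp1 (-0.997 ± 0.238), Rps15a (-0.96 ± 0.25) and Rpl37 (-0.81 ± 0.22) fell.

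Adjusted over the list alone, the counts were the same except in 7 of these lists. They were 2 higher and 2 lower for erythroid genes, 1 and 2 for immediate early genes, 2 and 2 for the glucocorticoid response, 3 and 4 for proliferation, 1 and 7 for ribosomal proteins, 1 and 4 for the proteasome, and 0 and 4 for antioxidant genes. Of the genes named for the 15 lists, Rps16 alone passed with array weights, and the others had an adjusted p from 0.0721 to 0.914.

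**Figure D3:**
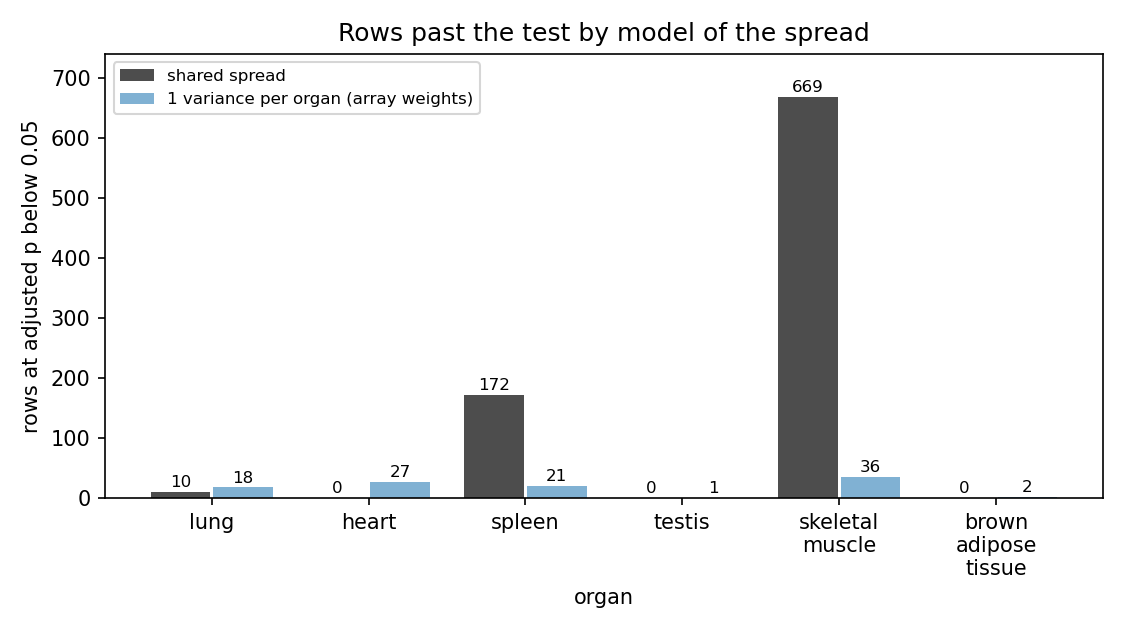
Number of rows at an adjusted p below 0.05 (vertical axis, from 0) in each organ, with a spread shared by all organs (dark bars) and with array weights, 1 variance per organ (light bars). Skeletal muscle goes from 669 to 36 rows and spleen from 172 to 21, while heart goes from 0 to 27.

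In heart, no single gene passed the test (limma, 0 of 13844 rows, with 284 at an unadjusted p under 0.05 against 692 by chance). Oxidative phosphorylation shifted down slightly, with a median of -0.15 over 54 genes, 44 of them below 0 (camera adjusted p = 0.025, and adjusted p = 0.565 with an estimated correlation). It did not pass without replicate 1, 3 or 4 of the organs (adjusted p of 0.386, 0.121 and 0.141) or with arrays centred only (0.169). Relative to all genes on the array, the list median was -0.03 and 0.09 with the mutant pool in Cy5, and -0.25 and -0.24 with it in Cy3. None of its members passed over all genes or over the list alone. Atp5h, a subunit of ATP synthase, had the largest ratio of the list, -1.97 ± 0.56, followed by Ndufs8 (1.0), Atp5k (0.70) and Ndufb5 (0.64). The largest ratios with 1 sign on every array were 2.61 ± 0.78 for Cd5l, a macrophage product, and -3.33 ± 0.82 for Vstm2l. They were followed by Irs3 (2.54), Vipas39 (2.42), Patl1 (2.22) and Klhl30 (2.17), and by Pla2g12a (-2.66), Sigirr (-2.58), Zcchc14 (-2.43) and Lnpk (-2.41).

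Array weights, which give heart a smaller variance, called 27 rows in heart, 10 higher and 17 lower. Among them were Cd5l (adjusted p = 0.0221), Sigirr, an inhibitory receptor of interleukin signalling (0.0168), Vstm2l (0.0221), Atp5h (0.0221) and Nr4a1 (0.0378). Every other setting tried gave 0 in heart. In simulated data with the organs' real spreads, the shared model recovered 41.8% of changes of log2 size 2 in heart, against 74.6% with array weights.

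In brown adipose tissue, genes of the skeletal muscle list were higher in the mutant pool. The list median was 0.54 over 21 genes, 17 of them above 0 (camera adjusted p = 1.75e-12, and 1.21e-05 with an estimated correlation). It was 1.01 after centring and scaling, which enlarges the ratios of this organ. No member passed singly, over all genes or over the list alone. The largest ratios were those of Mylpf (1.24 ± 0.44), Casq1 (0.94 ± 0.46), Tnnt3 (0.82 ± 0.43) and Eno3 (0.76 ± 0.81). By limma 0 of 15223 rows passed, with 102 at an unadjusted p under 0.05 against 761 by chance. With array weights 2 passed, Nr4a1 (adjusted p = 0.0107) and Ifi27l2a, an interferon-induced gene (adjusted p = 0.0391), a name outside the rule. With the shared spread Ifi27l2a stood at 1.60 ± 0.34. After centring and scaling 5 passed. In simulated data with the organs' real spreads, the shared model recovered 34.3% of changes of log2 size 2 in this tissue, against 56.7% with array weights. The 0 rows are therefore no sign that nothing changed. The largest values with 1 sign on every array were those of Xrcc6 (2.09), Fam83h (1.86), Ccdc184 (1.84), Adam23 (1.76) and Surf6 (1.73), and of Troap (-2.85), Wnt7b (-2.81), Erg28 (-2.29), Rapsn (-2.12) and Prmt1 (-1.92). The list of brown fat genes did not shift in this tissue.

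In testis, no gene and no list passed (limma, 0 of 13564 rows, with 492 at an unadjusted p under 0.05 against 678 by chance). The lists of steroid synthesis, germ cells and Sertoli cells did not shift. The largest ratios with 1 sign on every array were those of Tpsb2, a mast cell protease (3.65 ± 1.08), Prmt1 (3.17 ± 1.12), Fbl (3.07), Fndc3c1 (2.75) and Tex44 (2.68), and of B3gat1 (-3.41 ± 1.07), Kirrel2 (-2.83), Treml2 (-2.75), Itm2c (-2.69) and Arhgef18 (-2.64). An organ-specific dye term and array weights each gave 1 row, and centring and scaling gave 7.

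Across organs, no gene passed over the 6 organ means (limma, 0 of 7553 rows, smallest adjusted p 0.702, with 431 at an unadjusted p under 0.05 against 378 by chance). Nr4a1 had a mean of -0.79 ± 0.18 and was below 0 in all 6 organs. The largest positive means with 1 sign in all organs were those of Rps16 (1.02 ± 0.42), Cpeb4 (0.90), Gemin2 (0.85), Acsl3 (0.79) and Plin1, a coat protein of lipid droplets (0.77 ± 0.19). The largest negative ones were those of Tff2 (-1.04 ± 0.49), Tex45 (-0.92), Pappa (-0.86 ± 0.19), N6amt1 (-0.84) and Emc8 (-0.83). Rps16 ran from 0.045 to 3.55 over the organs, highest in skeletal muscle, and Tff2 from -4.14 in spleen to -0.11. Signs were equal in all organs for 6.20% of rows, against 3.125% if signs were independent.

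Between organs, the ratio of 169 of 7553 rows differed (limma F test). The farthest organ from the median was skeletal muscle for 127 rows and spleen for 31. The 10 genes with the smallest adjusted p were the pancreas genes Zg16 (1.24e-08), Cela3b (4.76e-07), Ctrl (6.44e-07), Ctrb1 (1.19e-05), Cpa1 (2.35e-05) and Pnliprp1 (0.000741), the ribosomal gene Rpl35 (1.92e-06), all farthest in spleen, and Dcaf13 (0.000201), Ago2 (0.000504) and Fam120b (0.000741), farthest in skeletal muscle. With array weights 72 rows differed, after centring and scaling 27, with arrays centred only 100 and with probes singly 328. Without replicate 1, 2 or 3 of every organ the counts were 47, 40 and 48.

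In all, 9 of 216 pairs of list and organ shifted, 1 up and 8 down, and 5 of them with an estimated correlation. These 5 were the pancreas list in spleen, the skeletal muscle list in lung and in brown adipose tissue, and heat shock in lung and in spleen. For the pancreas list and for heat shock the estimated correlation lay below the preset 0.01, at 0.00915 and 0. It was no stricter check there. The number was 16 with only complete rows, 10 after centring and scaling, 11 with array weights, with no dye term or with camera on ranks, and 6 with arrays centred only, with the separate mode kept or without any 1 of the 4 replicate numbers.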

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

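The tests of the patterns weighed in this part, on the pancreas genes, the skeletal muscle list and the number of genes in skeletal muscle, were chosen after the results were seen, while the regroupings of arrays were fixed before.

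On 4 of 64 groups of 4 arrays, 1 array stood far from the other 3, where chance gives about 3.2. In lung, Tnnc2 lay at -6.74 on replicate 2 and between -2.74 and -1.91 on the others, a gap of 0.8293 of the whole range. In spleen, Tomm34 lay at 5.86 on replicate 3 and between 1.43 and 2.16 on the others (0.8334). Clps lay at -8.25 on replicate 2 of spleen and between -5.11 and -4.70 on the others (0.8854), and Tff2 at -5.72 against -3.72 to -3.42 (0.867).

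The ratios of 10 genes differed most between organs by limma's F test. The adjusted p was 1.24e-08 for Zg16, 4.76e-07 for Cela3b, 6.44e-07 for Ctrl, 1.92e-06 for Rpl35, 1.19e-05 for Ctrb1, 2.35e-05 for Cpa1, 0.000201 for Dcaf13, 0.000504 for Ago2, and 0.000741 for both Fam120b and Pnliprp1. The medians of the skeletal muscle list and of the pancreas list also differed between organs (permutation of the organs among arrays of 1 dye orientation, adjusted p = 0.00275 for each, over the 5 lists that shifted in some organ). These lists were picked for a shift in an organ of the same arrays, so this test is no independent support. Outside the comparisons lie the 4874 values of the separate mode, which all have the sign of Cy5 over Cy3.

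The pancreas genes were lower in the mutant spleen pool, or higher in the wild-type one. A dye bias would turn the list median with the dye, but relative to all genes it was -4.96 with the mutant pool in Cy5 and -3.70 in Cy3. Pancreatic tissue in the wild-type spleen pool and a difference of the genotypes in spleen itself cannot be told apart and both stay open. That 90.9% of the measured list lay below -1 restates the pattern and would come out the same under either.

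Genes of the skeletal muscle list were lower in lung and higher in brown adipose tissue. A dye bias is argued against in both, since the medians relative to all genes kept their sign with the dye, at -0.904 or beyond in lung and at 0.445 or above in brown adipose tissue. Unequal amounts of carried-over muscle and a difference of the genotypes cannot be told apart in either tissue and both stay open. The shares of members above the median of all genes in brown adipose tissue, 85.7%, and below it in lung, 68.4%, restate the shifts and decide nothing.

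Skeletal muscle had the most genes past the test, for which no biological explanation was tested. Array-wide shifts are argued against as the whole cause, since 552 rows passed after each array was centred, 466 of them among the 669. The balance of higher and lower was different, and part of the 669 no longer passed. A larger error between hybridisations in this organ than a shared spread assumes may account for part of the 669, since 36 passed with a variance of its own. In simulated data with this spread and 200 true changes, 118 of 232 calls were false with the shared spread and 2 of 61 with array weights. That simulation gave all arrays of an organ 1 spread, the form that array weights fit, and so favoured them. The real muscle arrays differed in spread, with a scaled median absolute deviation from 0.964 to 1.83. Array weights also recovered fewer true changes of log2 size 2, 22.4% against 55.2%, so neither count is the number of true changes.

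Regrouping could not settle the counts within an organ, since the 4 arrays allow 8 sign patterns and 1 of 8 is above 0.05. Only the real pattern, 1 of 8, gave as many in lung (10, highest other 0), in spleen (172, highest other 152) and in skeletal muscle (669, highest other 360). In heart, testis and brown adipose tissue the real count was 0 (limma), as for all 8 patterns. There 284, 492 and 102 rows had an unadjusted limma p under 0.05, where chance gives 692, 678 and 761. With array weights 27, 1 and 2 passed the test. Across organs the real count was 0 by limma, with 431 at an unadjusted p under 0.05, and all 32 sign patterns gave as many. Of 100 regroupings of the arrays among organs, 1, the real one, gave as many as the 169 rows that differed between organs, and the highest other gave 3. This excludes a chance assignment of arrays to organs, but regrouping also mixes organs of unequal spread, so it does not tell differences in ratio from calls due to the larger error in skeletal muscle, the farthest organ for 127 of the rows. With array weights 72 differed, and in simulated data with the organs' own spreads, limma's F test called 0 rows with no true change and 24 false ones beside 200 true changes in spleen. For shifted lists 1 of 100 sign patterns, the real one, gave as many as the 9, and the highest other gave 8. Turning single arrays of an organ leaves part of a real shift in place, so these patterns are no clean reference. Chance is therefore not excluded for the number of lists, and nothing is said on any single list. Of the 9, 4 did not pass with an estimated correlation. Without any 1 of the 4 replicate numbers 6 lists shifted, a count that other patterns also reached.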

How the results depend on the processing

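Keeping the separate mode, centring without scaling, array weights for lists, and leaving out the 2 most shifted skeletal muscle arrays or the pancreas genes of spleen were chosen after seeing the data. So was leaving the separate mode out of the main analysis. Signs were compared for 154 values of genes in an organ. None turned with array weights, an organ-specific dye term, arrays centred only or each organ alone. None of the 151 values measured without heart replicate 2 turned either. For a gene measured on all arrays of an organ, array weights, an organ-specific dye term and the organ alone leave the ratio unchanged. The same holds outside heart without heart replicate 2. The sign of such a gene could not turn, so these settings tested signs only where a value was missing or, without heart replicate 2, in heart. Probes singly were compared only for genes with 1 probe, where the ratio cannot move, and some genes with several probes have probes of opposite sign. Across organs 0 rows passed under every alternative run (limma, 431 at an unadjusted p under 0.05). With array weights 78 values of genes in an organ kept their side of the threshold, 71 lost it and 5 gained it. With arrays centred and scaled 78 kept it, 72 lost it, 2 gained it and 2 turned sign. Of single array omissions 444 kept it, 85 lost it, 2 gained it and 7 turned sign. Unless said otherwise, the cause was not tested. Signal over background is not in the deposited values, so what it limits is unknown.

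With array weights the rows past the test were 18 in lung, 27 in heart, 21 in spleen, 1 in testis, 36 in skeletal muscle, 2 in brown adipose tissue and 72 between organs. With arrays centred and scaled they were 21 in spleen, 7 in testis, 60 in skeletal muscle, 5 in brown adipose tissue and 27 between organs. An organ-specific dye term gave 25 in lung and 1 in testis. Arrays centred only gave 5 in lung and 100 between organs. Probes singly gave 305 in spleen and 328 between organs. Each organ fitted alone gave 0 in lung, 0 in spleen and 0 in skeletal muscle, with 4 arrays and no spread shared between organs. Without the 2 most shifted skeletal muscle arrays 300 passed there, with fewer arrays. Without pancreas genes 151 passed in spleen. Complete rows only gave 16 shifted lists, and an estimated correlation gave 5. With the replicate block the counts were 8 in lung, 120 in spleen, 572 in skeletal muscle, 0 in the other 3 organs, 135 between organs and 9 lists. The residuals of the model gave no sign that the replicate numbers pair the arrays, which does not exclude it. On arrays with the same number they correlated across genes at a median of -0.0825, against -0.0762 for other numbers of the same dye orientation.

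Leaving out 1 array gave 8 (without replicate 2) to 22 (without replicate 1) in lung, and 187 (without replicate 2) to 300 (without replicate 4) in spleen, with 289 without replicate 1. Leaving out a replicate number gave 40 (without replicate 2) to 116 (without replicate 4) between organs. Nr4a1 ranged from -0.507 to -0.148 (without replicate 3) in lung, from -0.736 to -0.609 in heart and from -0.811 to -0.640 in spleen. Without testis replicate 2 or skeletal muscle replicate 3 it gave no value, and it has 1 probe, so probes singly move nothing.

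Scaled, Nr4a1 was at -0.437 in spleen, -0.787 in skeletal muscle and -1.82 in brown adipose tissue. With the separate mode kept, Nr4a1 was at -0.672 in heart, -0.748 in spleen, -1.99 in skeletal muscle and -1.14 in brown adipose tissue without passing, and at 4.13 in testis (limma, unadjusted p = 0.0309), where 1 of its values lies in that mode. Also with the separate mode kept, Hspd1 was at 1.08 in lung, Irs3 at -2.46 in heart, and Fgf12 at 0.208 and Frmpd1 at 1.90 in skeletal muscle.

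With no dye term Nr4a2 was at -0.458 in lung and 0.190 in skeletal muscle, and Nr4a3 at -0.599 in brown adipose tissue. With the replicate block Nr4a2 was at -0.00877 in lung and -0.129 in brown adipose tissue. Scaled, Nr4a3 was at 0.614 in testis and -0.0927 in brown adipose tissue. Leaving out 1 array, Nr4a2 ranged from -0.0165 to 0.373 in lung and from -0.0015 to 0.604 in brown adipose tissue. Nr4a3 ranged from -0.449 to 0.0189 in testis, from -0.469 to 0.923 in skeletal muscle and from -0.734 to 0.804 in brown adipose tissue. Atp5c1 ranged from -3.57 to 2.53 in spleen, and Eno3 from -0.361 to 1.48 in brown adipose tissue.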

Other observations

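The genes of the next 2 paragraphs were chosen after their values were seen, while the test on the neighbours of Nr4a1 was fixed before.

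In heart, array weights called the chemokines Ccl8 (-1.44 ± 0.49, adjusted p = 0.0103) and Ccl17 (-1.08 ± 0.33, adjusted p = 0.0349), the class I histocompatibility gene H2-K1 (0.67 ± 0.22, adjusted p = 0.0213), Herpud1, of protein degradation at the endoplasmic reticulum (-0.71 ± 0.24, adjusted p = 0.0213), and Txnip, an inhibitor of thioredoxin (-0.63 ± 0.25, adjusted p = 0.0221). The SE given here are those of the shared spread, not of the array weights. By limma with a shared spread each had an adjusted p of 1. Txnip was below 0 in all 6 organs, with a mean of -0.44 ± 0.12 (limma adjusted p = 0.702).

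The 3 highest ratios past the test in skeletal muscle belonged to probes without a gene symbol, probe 19294 (6.39), probe 121 (5.30) and probe 92 (4.85). All 3 passed with array weights as well.

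A segment of the chromosome of the embryonic stem cell strain, carried along with the disrupted gene, could change the neighbours of Nr4a1 in every organ. The median size of the moderated statistic over organ means was 0.783 for the 50 measured genes before Nr4a1 and the 15 after it on chromosome 15. Over 10000 random windows of the same shape the median was 0.872 and the 95th percentile 1.03, which puts the neighbours at percentile 23.4. These values argue against a change that recurs over organs in most of these neighbours. A median hardly moves with a few genes, so changes in some neighbours, or in single organs, stay open.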
